A study of Mus musculus with 16 samples.

How the data were processed

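The series holds single-cell RNA and T cell receptor (TCR) sequencing of sorted CD8+CD44+ T cells of C57BL/6 mice with melanoma-associated vitiligo, taken from the tumor-draining lymph node and from matched skin lesions. Its 16 samples are 4 libraries (lymph node RNA, lymph node TCR, skin RNA and skin TCR), each sequenced on 4 lanes. Lanes of a library share its cells, so they are not biological replicates, and each tissue counts as 1 library. The number of mice pooled is not given in the sources used here. Per the labels' protocols, lymph nodes were dissociated mechanically through a 40 µm filter, whereas skin was digested with 3 mg/mL collagenase and 0.2 mg/mL DNase at 37 °C for 45 minutes.

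The deposited gene table gives whole-number UMI counts per gene and cell for the lymph node, with the lanes pooled by the authors. The submitters' processing notes name Bowtie, RSEM and the mouse build mm10, without a version or a role for either tool. The table had already been reduced: no cell reached a mitochondrial share of 5%, the highest being 4.99%, no cell had more than 2992 genes, and every gene was seen in at least 14 cells. The deposited receptor tables list assembled contigs with their V and J segments, CDR3 sequences and UMI counts, 1 table per tissue. The tissue of each table was taken from its own name. Skin RNA was not analysed here, so expression was compared only among lymph node cells.

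Contigs were kept when they were productive, full-length, of high confidence and of a TRA or TRB chain. This left 7423 of 9927 contigs in the lymph node and 3603 of 4545 in skin, with a median of 5.0 and 3.0 UMIs. A clone was defined by identical TRB and TRA CDR3 nucleotide sequences, in cells with exactly 1 TRB and 1 or 2 TRA sequences, taking the contig with most UMIs of each chain. Expanded clones held at least 2 cells in the tissue. Numbers of clones were compared after 1000 draws of 1322 lymph node cells, the number of skin cells with a clone. V segments were counted once per clone.

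Cells of the gene table were joined to lymph node clones by barcode. For each gene, UMI counts were summed over lymph node cells of clones also found in skin (shared clones) and over those of clones not found in skin (LN-only clones), and divided by the total to give CPM, counts per 1e6. The log2 ratio used for ranking and for list medians had a prior of 1 CPM on both sides. Gene intervals are exact 95% intervals of the ratio of the counts without the prior. Shares carry exact Clopper-Pearson 95% intervals, and list medians carry intervals from 1000 Poisson redraws of the summed counts. With 1 library per tissue there was no test, and cells are not replicates: all intervals cover counting error only. Where a side had 0 counts, a limit was computed at a floor of 3 counts summed over that side, which was 44.4 CPM for shared-clone cells.

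For each of the gene lists fixed before the data were examined, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of this library. The named genes were chosen by a rule also fixed before the data were examined. They are the 12 highest and 12 lowest log2 ratios among genes with a UMI in at least 10% of cells of the higher side and at least 50 UMIs over both sides, with the same direction without the largest shared clone and with every clone weighted equally. TCR and immunoglobulin segments, mitochondrial genes and ribosomal protein genes were left out. The rule adds the 2 highest and 2 lowest members of each list described with at least 50 UMIs, and the sort genes Cd3e, Cd8a, Cd8b1, Cd44 and Cd4. For the receptors it takes the 5 TRBV and 5 TRAV segments with most clones in each tissue, the 3 of each that differ most, and the 5 shared clones with most cells.

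Cells were clustered with scanpy 1.11.5 by the Leiden method (igraph 0.11.9) on 2000 variable genes, without 62 receptor segment genes, with 30 components, 15 neighbours and a resolution of 1.0. Clusters are referred to by number. Scrublet, run through scanpy, marked 0 of the 3266 cells as doublets, although 394 of the 3744 lymph node barcodes carried at least 2 TRB sequences. Such barcodes were not given a clone. Shares of cells with a UMI were also computed after thinning each cell to 1500 UMIs, which left out 6 shared-clone and 45 LN-only cells. Gene positions are from GENCODE M21, on the build mm10, and 9361 of the 9428 gene names matched it.

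The count comparison was tested on simulated data with the totals of the shared and LN-only sides, 8339 genes and 200 genes changed by known amounts, 50 at each of 4 sizes. Genes raised by a log2 ratio of 2.0 had a median estimate of 1.98. Genes lowered by 2.0 had a median estimate of -3.76, because many had 0 counts in the shallower side, so negative log2 ratios with the prior overstate the size of a fall. Of 200 unchanged lists of 15 genes, 5 lay outside the central 95% of random lists. Each gene was drawn on its own with counting error only, without variation between cells or clones and without genes that vary together. The simulation therefore cannot show how often real lists of such genes would lie outside. Other cell types in the gate were looked for with marker genes fixed with the lists. The count comparison had first been run on the real table before this simulation was made, and was not altered by it. Alternatives covered the clone definition, contig support, cells with several chains, the expansion threshold, the weighting of clones, scaling, the prior, low counts, depth, cluster resolution and the number of components. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.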

Results

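T cell receptors and transcriptomes were measured in sorted CD8+CD44+ T cells of 16-week-old mice with melanoma-associated vitiligo, an autoimmune loss of pigment that accompanies the response to the tumor, 45 days after tumor surgery. Cells came from the tumor-draining lymph node and from matched vitiligo skin. The lymph node gene table held 3266 cells and 9428 genes with 14556622 UMIs, at a median of 4423 UMIs per cell (range 461 to 12576). The receptor tables held 3744 barcodes in the lymph node and 1986 in skin, of which 2548 and 1322 had a clone. Each tissue was 1 library, so no difference below has a replicate check, and all intervals cover counting error only.

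The first comparison asked how clonal the T cells of each tissue were. Skin was dominated by expanded clones, and the lymph node by clones seen once. In skin, 804 of 1322 cells (60.8%, interval 58.1 to 63.5) belonged to 183 expanded clones. In the lymph node this held for 121 of 2548 cells (4.75%, 3.96 to 5.65) in 59 clones. The lymph node share was 1.76% with only contigs of 3 or more UMIs, 10.6% with the TRB sequence alone and 0.353% when expansion required 3 cells. At an equal number of 1322 cells, the lymph node held a mean of 1305 clones (1292 to 1314 over the draws) and skin held 701. The largest clone had 88 cells in skin, 6.66% of its cells (5.37 to 8.14), and 3 cells in the lymph node. The 10 largest skin clones together held 236 cells, or 17.9%.

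**Figure D1:**
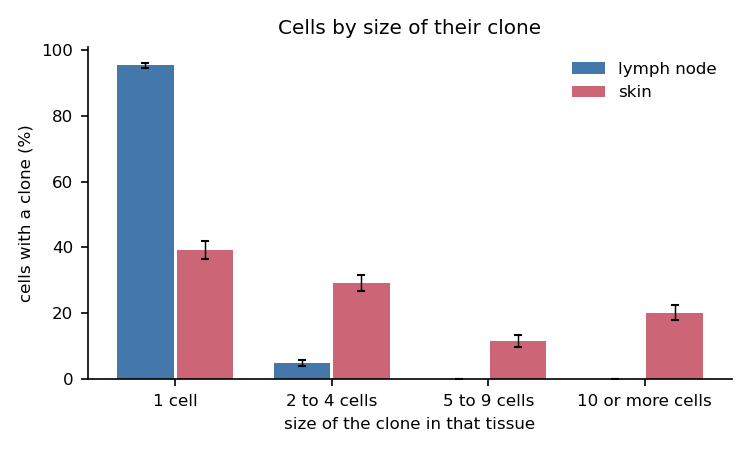
Percent of cells with a clone (y axis) by the size of their clone in that tissue (x axis), for lymph node and skin. Bars are shares and error bars exact 95% intervals; 20.2% of skin cells and none of 2548 lymph node cells were in clones of 10 or more cells.

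The next comparison asked which clones were present in both tissues. There were 31 shared clones. They made up 40 of 2548 lymph node cells (1.57%, 1.12 to 2.13) and 231 of 1322 skin cells (17.5%, 15.5 to 19.6). Sharing was more frequent for skin clones of 5 or more cells than for those with 1 cell. It was 1.74% (0.798 to 3.27) of 518 skin clones with 1 cell, 7.43% (3.77 to 12.9) of 148 clones with 2 to 4 cells, 31.8% (13.9 to 54.9) of 22 clones with 5 to 9 cells and 30.8% (9.09 to 61.4) of 13 larger clones. In the lymph node, 24 of 2427 clones with 1 cell (0.989%, 0.635 to 1.47) and 7 of 59 expanded clones (11.9%, 4.91 to 22.9) were also in skin. Larger clones are more easily seen in both samples, so part of this order follows from sampling.

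The shared clone with most cells carried the TRA CDR3 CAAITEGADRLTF and the TRB CDR3 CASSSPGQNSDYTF, with 88 cells in skin and 3 in the lymph node. Next came the clone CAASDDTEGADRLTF with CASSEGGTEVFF, with 23 skin and 3 lymph node cells, and CALERSGSGGKLTL with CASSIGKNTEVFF, with 17 and 2. The clones with the TRB CDR3 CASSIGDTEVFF and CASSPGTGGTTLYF had 10 and 9 skin cells and 1 lymph node cell each. Without the largest skin clone, an alternative chosen after seeing the data, shared clones made up 11.6% of skin cells. With only contigs of 3 or more UMIs, 13 clones were shared, with 0.818% of lymph node cells, and requiring 2 cells in each tissue left 6, with 0.549% of lymph node and 10.6% of skin cells. With the TRB sequence alone 47 were shared, with 2.39% of lymph node cells, but this also takes in 671 lymph node and 366 skin cells without a TRA; among cells with a clone, 38 TRB nucleotide sequences were in both tissues.

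**Figure D2:**
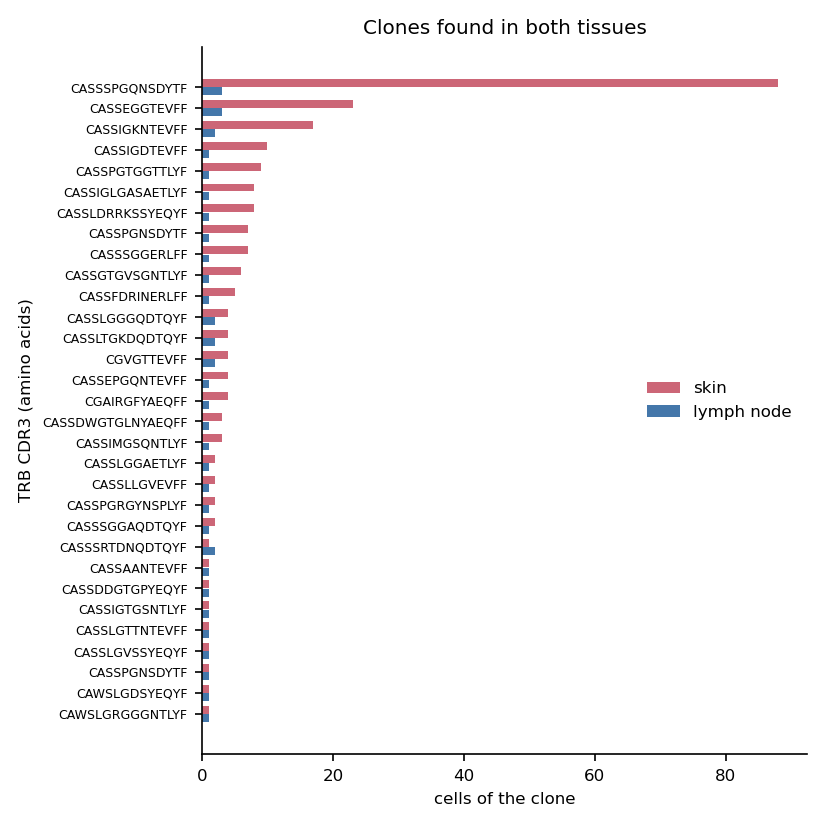
Cells per clone (x axis) in skin and lymph node for the 31 clones found in both tissues, named by TRB CDR3 amino acids (y axis). The first clone had 88 skin cells and 3 lymph node cells.

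V segment use was compared with each clone counted once. TRBV19 was the segment with most clones in skin, at 12.8% (10.5 to 15.5) of 701 clones against 5.67% (4.80 to 6.66) of 2486 in the lymph node, a ratio of 2.26. TRBV12-2 was lower in skin, at 2.43% (1.42 to 3.85) against 8.61% (7.53 to 9.78). TRBV3 was at 4.85% (3.38 to 6.71) of skin clones against 8.0% (6.97 to 9.14), although it took 12.8% of skin cells and 8.16% of lymph node cells, since the largest skin clone used it. The contigs assigned jointly to TRBV12-2 and TRBV13-2 made up 7.28% of skin and 9.41% of lymph node clones. TRBV12-1, TRBV16 and TRBV29 had overlapping intervals in the tissues, at 6.70%, 6.85% and 6.42% of skin clones and 7.76%, 7.12% and 5.15% of lymph node clones.

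Among TRAV segments, TRAV3D-3 held most skin clones (5.85%, against 4.30% in the lymph node) and TRAV12-2 most lymph node clones (5.47%, 4.61 to 6.44, against 3.00%, 1.86 to 4.54, in skin). TRAV12D-3 was at 3.42% in skin and 5.19% in the lymph node, and TRAV6N-7 at 3.28% (2.09 to 4.88) and 1.69% (1.22 to 2.28). TRAV6-6 was at 4.42% and 3.62%, TRAV13-1 at 2.71% and 4.14%, and TRAV12D-2 at 3.28% and 2.33%. Mouse TRAV segments have near-identical duplicated copies, so assignments within a family are uncertain.

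**Figure D3:**
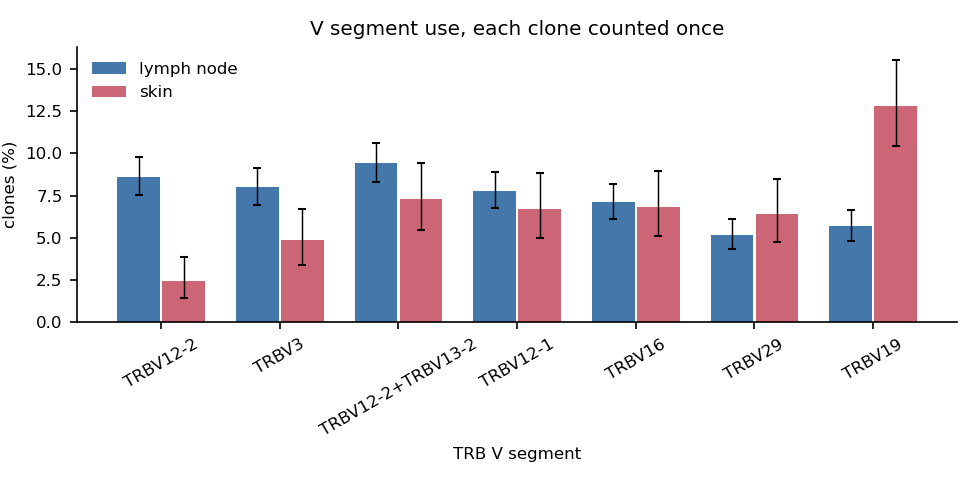
Percent of clones (y axis) using each named TRB V segment (x axis) in lymph node and skin, each clone counted once, with exact 95% intervals. TRBV19 stood at 12.8% in skin and 5.67% in the lymph node.

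Lymph node cells of shared clones were then compared with lymph node cells of LN-only clones, which asks whether clones also present in lesions had another expression state in the node. The gene table held 28 of the 40 shared-clone cells, of 26 clones, with 67509 UMIs, and 2107 LN-only cells with 9595107 UMIs. From the skin cells in clones seen once, 60.8% of further skin cells would be expected in clones already seen. LN-only clones may thus include skin clones that were not sampled. Shared-clone cells had more Gzmb, Gzma, Itgae, Itga1 and Ccr10, and the recirculation and stem-like memory lists were lower in them. Gzmb, a cytotoxic granule protease, was at 1022 CPM against 8.13 (log2 ratio 6.97, 6.49 to 7.46), and Gzma at 815 against 13.8 (5.89, 5.41 to 6.35). Itgae, the CD103 integrin chain that binds epithelial cadherin, was at 726 against 32.5 CPM (4.48, 4.01 to 4.92). Ly6c2, a marker of memory cells in circulation, was at 104 against 2162 CPM (-4.38, -5.70 to -3.34). The shared-clone cells were shallower, at a median of 2281 UMIs against 4556.

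The other genes with the highest ratios were Lgals3 (log2 ratio 6.48, 6.00 to 6.96), S100a4 (5.35, 5.04 to 5.65), Itga1 (5.29, 4.18 to 6.28), Fgl2 (5.10), Ccr10 (4.99), Cish (4.64), Slamf1 (4.54), the transcriptional regulator Id2 (4.53, 4.24 to 4.81) and Capg (4.37). Gzmb had a UMI in 50% of shared-clone cells, in 13 clones, and S100a4 in 82.1%, in 22 clones. Thinned to 1500 UMIs, Itgae had a UMI in 59.1% (36.4 to 79.3) of 22 shared-clone cells and 4.70% (3.83 to 5.71) of 2062 LN-only cells, against 64.3% and 9.30% before thinning. On mm10, Gzmb lies on chromosome 14 from 56258838 to 56262260, Itgae on chromosome 11 from 73090583 to 73147446, Itga1 on chromosome 13 from 114953096 to 115101964 and Ly6c2 on chromosome 15 from 75108158 to 75111970.

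The 12 lowest genes all had 0 UMIs in shared-clone cells, so only limits can be given, against a floor of 3 counts over that side. Ms4a4c was at least 4.46-fold lower, Dapl1 at least 3.97-fold, Itm2a at least 2.95-fold, the granzyme Gzmm at least 2.45-fold and Atic at least 2.27-fold. For Gpr18, Gemin7, Arl5c, A930005H10Rik, Fdx2, Tmem108 and Il6st the limits lay between 1.44-fold and 1.91-fold.

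Of the gene lists, the effector list stood highest, with 10 of 11 measured members higher in shared-clone cells. Its median log2 ratio was 3.86 (3.69 to 4.55), at percentile 100 of random lists. Its lowest members with at least 50 UMIs were Klre1 (1 UMI in shared-clone cells, -0.39, -5.70 to 2.11) and Tbx21 (0.97, -0.48 to 2.10). Residency genes had 15 of 19 higher and a median of 1.52 (0.94 to 2.45, percentile 100). Itga1 and Itgae were the highest members and Xcl1 (1 UMI, -2.80, -8.11 to -0.32) was lower. Cd69, a member named after its value was seen, was at 163 against 284 CPM (-0.80, -1.80 to 0.04). Ctla4 had 0 UMIs in shared-clone cells, with a limit above 0. Chemokine receptors had 7 of 10 higher (median 2.86, 2.10 to 3.26, percentile 100). Among them were Ccr10 and Cxcr6, the latter at 1703 against 136 CPM (3.65, 3.36 to 3.92). Cxcr5 and Cxcr4 had 0 UMIs in shared-clone cells, with limits above 0 (1.28 and 1.46), so their direction was not detectable. Cytotoxicity genes had 9 of 13 higher (0.78, 0.23 to 1.21, percentile 97.8), while Gzmm had 0 UMIs and Lamp1 was at -0.95 (-2.83 to 0.41). Cytokines and chemokines had 10 of 11 higher (1.13, 0.94 to 2.47, percentile 98.95), with Ifng at 3.79 (2.42 to 4.90) and Ccl4 at 2.93 (2.18 to 3.59). Ifng had a UMI in 21.4% of shared-clone and 2.94% of LN-only cells, but after thinning in 0 of 22 (up to 15.4%) and 1.12%. The interferon response list had 12 of 14 higher (1.32, 0.94 to 1.68, percentile 100), with Ly6a at 3.52 (3.19 to 3.82). Usp18 was at -0.44 (-3.49 to 1.43) and Oasl2 had 0 UMIs in shared-clone cells, with a limit above 0 (1.72).

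Markers of other cell types were also summed. B cell markers were at 370 CPM in shared-clone and 226 in LN-only cells, and myeloid markers at 370 and 201, with 25 UMIs each in shared-clone cells. Of the 25 B cell marker UMIs, 18 were Cd74 (267 against 16.7 CPM) and 4 were Ighm, which was lower (-1.56, -3.43 to -0.20). Ighd, H2-Ab1 and H2-Eb1 had 0, with limits above 0. Keratinocyte markers were at 14.8 and 15.9 CPM, and the 1 dendritic and 1 endothelial marker in the table had 0 UMIs in shared-clone cells. Plasma cell, stromal, melanocyte and erythroid markers were not in the table. NK markers were at 14.8 and 12.7 CPM, the 1 of 7 γδ T cell markers in the table at 29.6 and 24.4, with 2 UMIs in shared-clone cells, and CD4 T cell markers at 104 and 64.8, where all 7 UMIs of shared-clone cells were Cd40lg. Trgv2, a γ chain segment chosen after its values were seen, had a UMI in 24.3% (17.4 to 32.2) of cells with a contig in cluster 6, the cluster of 26 of the 28 shared-clone cells, and in 1.24% (0.865 to 1.72) elsewhere.

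Recirculation genes were lower in 15 of 22 members (median -1.32, -2.38 to -0.90, percentile 0.00), and stem-like memory genes in 12 of 15 (-2.12, -3.55 to -1.36, percentile 0.00). With genes of 0 UMIs at their limit these medians were -0.66 and -0.58. S1pr4 (1.14, 0.23 to 1.92), Samhd1 (1.42, 0.79 to 1.99) and Il7r (0.79, 0.39 to 1.17) went against their lists, as did Cx3cr1, also an effector list member (log2 ratio with the prior 6.12), named after its value was seen. The recirculation and stem-like memory lists overlap in part, so they are not independent. The same holds for the higher lists. Gzma and Gzmb are in the effector and cytotoxicity lists, and Ccl5 in the effector and cytokine lists. Cxcr6 is in the residency and chemokine receptor lists, and Itgae and Skil are in the residency and TGF-β lists. TGF-β response genes had 7 of 8 higher (1.12, percentile 98.8), with Smad7 lower at -0.27 (-2.15 to 1.09). Lipid uptake and oxidation genes had 5 of 5 higher (1.38, percentile 98.2). The 3 measured Tc17 genes were all higher (3.22, -1.42 to 4.29), among them Rora at 4.21 (2.69 to 5.44). With cells thinned to 1500 UMIs the TGF-β median fell to 0.40 (-3.69 to 0.94). The intervals of residency (1.35, -1.39 to 2.08), cytotoxicity (0.81, -0.31 to 1.05), cytokines (1.26, -1.43 to 1.66), lipid (1.51, -3.18 to 2.14) and Tc17 genes (3.39, -2.08 to 4.18) then also passed 0. Those of effector, chemokine receptor, interferon, recirculation and stem-like memory genes did not. Other alternatives moved medians by over 1.5 times: the TRB sequence alone gave -1.09 for stem-like memory and 0.59 for lipid genes, median-of-ratios scaling 0.35 for cytotoxicity, 0.69 for cytokines and 0.68 for TGF-β, and a prior of 10 CPM 1.69 for Tc17 genes.

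The lists of cell cycle (0.78, percentile 92.3), sort genes (0.51, percentile 88.6), glycolysis (-0.34, percentile 12), dissociation stress (-0.08, percentile 19.8), early activation (-1.44, percentile 20.8), NK receptors (-0.37, percentile 28.2) and inhibitory receptors (-0.45, percentile 25.8) lay within the central 95% of random lists. With genes of 0 UMIs at their limit, the last 4 had medians above 0, so their direction was not detectable at this depth. Within NK receptors, Klrk1 (4.23, 3.70 to 4.73) and Klrc1 (3.95, 3.26 to 4.57) were higher. Klra7 and Klra3 had 0 UMIs in shared-clone cells, with limits above 0 (0.54 and 0.74). Of the type 2 repair list only Gata3 was in the table (0.60, -1.29 to 1.96). Of the sort genes, Cd8a was at 1703 against 540 CPM (1.66, 1.38 to 1.92), Cd8b1 at 0.60 (0.36 to 0.84), Cd44 at 1.4 (0.44 to 2.22) and Cd3e at 0.42 (0.09 to 0.73), whose sign turns when the ratio is taken relative to the median-of-ratios shift of 0.44. Cd3d, also in the sort gene list, was lower (-0.52, -0.96 to -0.11), and Cd4 was not measured.

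**Figure D4:**
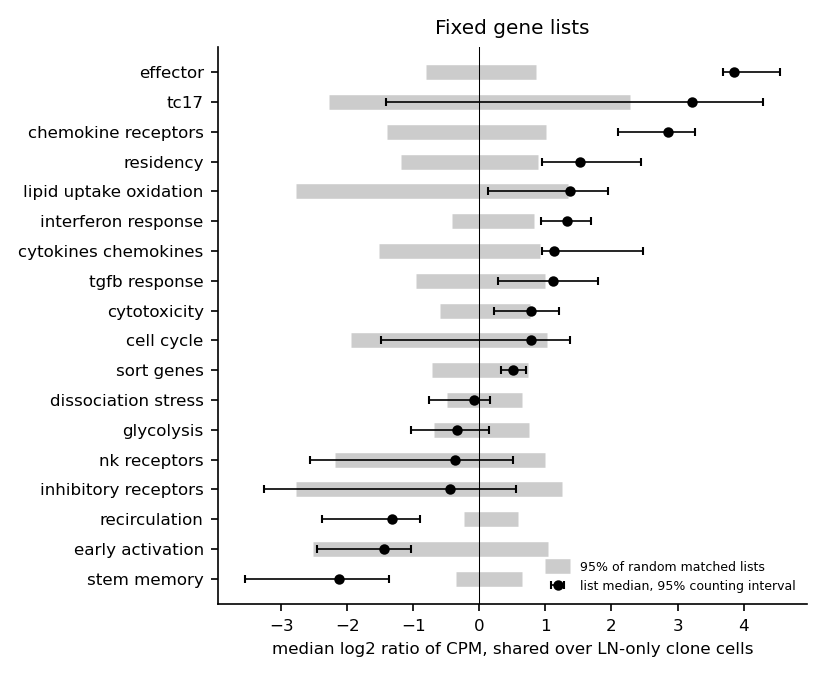
Median log2 ratio of CPM (x axis) of each fixed gene list (y axis) between lymph node cells of shared and LN-only clones. Points are medians with 95% counting intervals and grey bars hold 95% of random matched lists; the effector list stood at 3.86 and the stem-like memory list at -2.12.

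Against the 100 cells of expanded LN-only clones, the effector list again stood highest. These clones had at least 2 lymph node cells, whereas 24 of the 31 shared clones had 1, so clone size was not matched. The effector median was 4.40 (3.79 to 4.96), the residency median 2.0 (0.90 to 2.75), the chemokine receptor median 2.85 (1.87 to 3.44), the recirculation median -1.34 (-2.20 to -0.82) and the stem-like memory median -2.56 (-3.27 to -1.29). With genes of 0 UMIs at their limit the last 2 medians were -1.29 over 20 of 22 genes and -1.01 over 14 of 15. Genes with at most 3 UMIs on both sides were left out of these. Thinning gave a residency median of 1.04 and the TRB sequence alone a stem-like memory median of -1.26. The cytotoxicity list, at a median of 0.46 (-0.01 to 1.17) and percentile 86.0, lay within the random lists here, with 9 of 13 members higher and 4 lower. Among the higher members were Gzmb and Gzma (log2 ratios with the prior 7.81 and 6.65), with 1 and 2 UMIs in the expanded LN-only cells.

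The difference rested on cells of cluster 6, described next. In splits chosen after seeing the data, within that cluster the effector median was 1.23 and the residency median 0.71. The stem-like memory median was -1.73 and the recirculation median -1.20. With genes of 0 UMIs at their limit the last 2 medians were -1.04 over 13 of 15 genes and -0.75 over 18 of 22. Genes with at most 3 UMIs on both sides had no limit. Outside cluster 6 only 2 shared-clone cells remained, with 3605 UMIs. The effector and residency medians were then -2.37 and -2.87, so the higher lists could not be followed there.

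Clustering divided the lymph node cells into 7 clusters, and shared-clone cells were concentrated in cluster 6. It held 183 of 3266 cells (5.60%) and 26 of 28 shared-clone cells (92.9%, 76.5 to 99.1), of 24 clones, against 64 of 2107 LN-only cells (3.04%, 2.35 to 3.86). The remaining 2 shared-clone cells were in cluster 5. The leading genes of cluster 6 were Lgals3, Gzma, Itga1, Csf1, Cx3cr1, Anxa1, S100a4, Gzmb and Ccr10, which are among the genes compared above. Its 10 leading genes held 3 effector markers and 1 resident-memory marker, and its 50 leading genes held 3 of each, so it is not given a name. Summed resident-memory markers were at 1902 CPM in cluster 6 and 542 elsewhere, and summed effector markers at 1064 and 146. Cluster 5 was led by Wnt10a, Nrn1, Cd200, Izumo1r, Ctla4 and Lag3, and cluster 1 by Klra6, Klre1 and Klra7. Cluster 4 was interferon-responding-like, led by Rsad2, Ifit1 and Isg15. With the listed and named genes left out of the clustering, an alternative chosen after seeing the data, 27 of 28 shared-clone cells again fell in 1 cluster, which was wider and held 14.1% of LN-only cells. At resolution 0.6 the cluster with most shared-clone cells held 15% of LN-only cells.

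**Figure D5:**
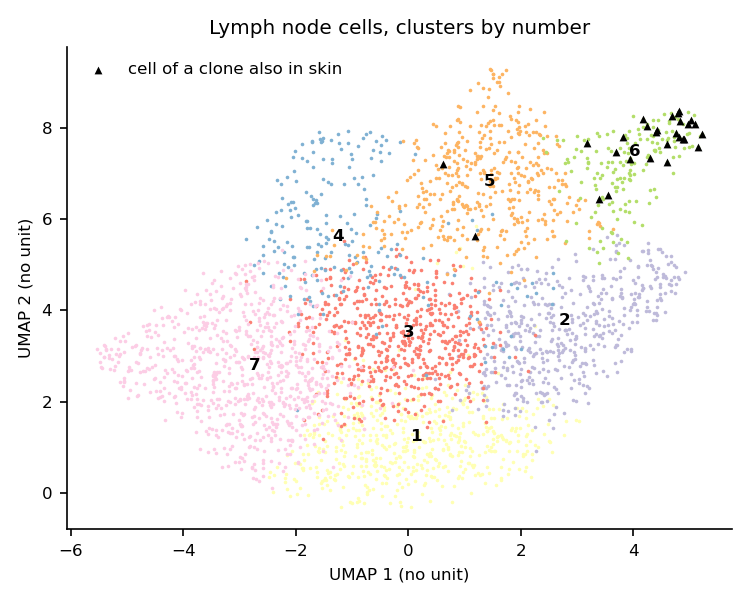
UMAP positions (both axes without unit) of 3266 lymph node cells coloured by cluster, with triangles for cells of clones also found in skin. Of 28 such cells, 26 lay in cluster 6 and 2 in cluster 5.

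Cells of expanded clones were found in every cluster. Expanded clones held 10 of 90 cells with a clone in cluster 6 (11.1%, 5.46 to 19.5), 1.74% (0.703 to 3.55) in cluster 1 and between 4.56% and 6.60% in the other 5 clusters. The interval of cluster 6 overlapped those of all clusters but cluster 1, which does not show an even spread. Of the 10 cells in cluster 6, only 2 were of LN-only clones. The cluster 6 share was 21.7% with the TRB sequence alone. That of the cluster with most shared-clone cells was 6.12% at resolution 0.6 and 5.85% when clustered without the listed genes. Expression in the lymph node against skin was not analysed here.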

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

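The comparison of cells with and without a contig was chosen after the data had been examined. The receptor comparisons leave out lymph node cells with no contig, and these were not evenly spread over the clusters. Of the 302 such cells, 43 were in cluster 6, which holds most shared-clone cells. They were 23.5% (17.6 to 30.3) of that cluster and 8.40% (7.45 to 9.44) of the other clusters. The 43 cells had a median of 1621 UMIs, against 2924 for cells of cluster 6 with a contig. Trac had a UMI in 58.1% (42.1 to 73.0) of them and in 53.6% (45.0 to 62.0) of those with a contig, and Cd8b1 in 93.0% and 99.3%. For Trbc2 these shares were 27.9% (15.3 to 43.7) without and 42.1% (33.9 to 50.8) with a contig. Itgae was at 490 CPM in the cells without a contig and 429 in those with a contig, Cxcr6 at 765 and 908, and Gzmb at 156 and 298. Gzmb had a UMI in 18.6% (8.39 to 33.4) and 30.7% (23.2 to 39.1) of them.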

How the results depend on the processing

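Leaving out the largest skin clone, splitting cells by cluster 6, and clustering without the listed genes were tests chosen after seeing the data, as was the bound by which the ratio of clone numbers counts as moved. Of 383 values under alternatives, 278 stayed within counting error of the reported value (for the number of shared clones, within 1.5 times), 87 moved, and 18 changed sign for a list outside the central 95% of random lists. These 18 come from splits by cluster 6 that leave 2 cells on a side, where 10, 13 and 4 lists in all had another sign than reported, values of 0 included. Of 247 gene list values under alternatives fixed before, 7 had the opposite sign, all of lists within the central 95%, among them NK receptors (0.53 against -0.37) with the TRB sequence alone, which also added cells, and cell cycle (-1.46 against 0.78) when thinned. Some alternatives could hardly have moved a value. Of the 278, 36 came from leaving out the largest shared clone, which was 2 of 28 cells. Another 3 came from leaving out barcodes with the same clone in both tissues, of which there were 0. No paired analysis was possible because each tissue is 1 library. A mitochondrial limit of 5% removed no cell, no doublet was called and no cluster was left out as another cell type, so changing these steps moved nothing. Except for fewer cells or contigs, the cause was not tested.

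With the TRB sequence alone, which also takes in 671 lymph node and 366 skin cells without a TRA and so compares 49 shared-clone with 2538 LN-only cells, 47 clones were shared, with 2.39% of lymph node and 24.9% of skin cells. Expanded clones then held 10.6% and 68.2% of cells, 21.7% of cluster 6 and 9.35% of the other clusters, and the ratio of clone numbers at equal cells was 2.14. List medians were 3.62 (effector), -1.09 (stem-like memory, and -1.26 against expanded clones), 0.53 (NK receptors, and 0.97), -1.01 (early activation) and 0.89 (interferon). With contigs of 3 or more UMIs, 13 clones were shared, with 0.818% of lymph node and 12.9% of skin cells, expanded clones held 1.76% and 50%, and the ratio was 1.55. Requiring 2 cells in each tissue left 6 clones, with 0.549% and 10.6% of cells. Requiring 3 cells for expansion gave 0.353% and 47.8%. Amino acid clones gave a ratio of 1.88. Without the largest skin clone, 11.6% of skin cells were shared and 58.0% expanded, and the ratio was 1.74.

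Median-of-ratios scaling gave medians of 0.69 (cytokines), 3.41 (effector), 0.89 (interferon) and 0.067 (sort genes), and against expanded clones -0.73 (glycolysis) and 0.096 (sort genes). Equal clone weights gave 3.43 (effector) and a prior of 10 CPM gave -0.41 (early activation). Thinning gave -2.54 (early activation) and, against expanded clones, -2.52 (early activation) and 0.099 (TGF-β). Leaving out members under 20 UMIs gave, against expanded clones, 2.03 (NK receptors) and -0.87 (cell cycle). Resolution 0.6 put 100% of shared-clone and 15% of LN-only cells in 1 cluster, 20 components gave 2.23% of LN-only cells and clustering without the listed genes 14.1%.

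Within cluster 6, against LN-only clones, the medians were 0.71 (residency), 0.20 (cytotoxicity), 0.66 (cytokines), 0.60 (chemokine receptors), 1.23 (effector), -0.20 (early activation), 0.70 (interferon) and 0.12 (sort genes).

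Outside cluster 6, 2 shared-clone cells with 3605 UMIs remain, so that 1 UMI is worth 277 CPM and genes with 0 UMIs set most medians. Those that changed sign were cell cycle (-2.29), residency (-2.87), cytotoxicity (-2.37), cytokines (-3.01), chemokine receptors (-4.20), effector (-2.37), interferon (-4.52), Tc17 (-1.60), lipid (-3.49) and TGF-β (-4.39). Recirculation (-4.75), inhibitory receptors (-3.39), stem-like memory (-5.03), NK receptors (-4.08), early activation (-2.71), glycolysis (-5.31), dissociation stress (-2.66) and sort genes (0.79) moved. Against expanded clones, residency (-2.20), cytokines (-3.04), chemokine receptors (-4.03), effector (-0.83), interferon (-4.80), Tc17 (-2.20), TGF-β (-4.10), cytotoxicity (-1.16), inhibitory receptors (-3.95), lipid (-3.95) and dissociation stress (-1.19) changed sign, and cell cycle and NK receptors differed in sign by a value of 0. Recirculation (-4.92), stem-like memory (-5.06), NK receptors (-3.95), early activation (-3.30), glycolysis (-5.25) and sort genes (0.81) moved.

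Within cluster 6, 2 cells of expanded LN-only clones remain, with 4030 UMIs. Against them recirculation (5.30) and stem-like memory (4.06), early activation (2.03) and sort genes (-0.31) changed sign. Residency (5.01), cytotoxicity (1.79), cytokines (4.06), chemokine receptors (6.0), inhibitory receptors (4.06), effector (2.12), interferon (5.95), cell cycle (4.54), lipid (5.01), TGF-β (4.54) and dissociation stress (2.78) moved. Depth limits falls most, since a gene at 0 among 67509 UMIs can still be at 44.4 CPM.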

Other observations

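The tests of sequences shared on both chains, of barcodes of lymph node cells and of dissociation stress genes were chosen after the data had been examined, as was the split by cluster 6. The tests of barcodes of skin cells, of TRB sequences, of a dominant clone and of clone size were fixed before.

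Within cluster 6 the 26 shared-clone cells still differed from the 64 LN-only cells. The effector list had a median log2 ratio of 1.23 (0.91 to 1.66, percentile 99.99) with 11 of 11 members higher. The stem-like memory list had one of -1.73 (-2.59 to -0.83, percentile 0.00) with 13 of 15 lower. With genes of 0 UMIs at their limit, the stem-like memory median was -1.04 over the 13 genes that had a limit. Recirculation genes were at -1.20 (-2.16 to -0.40), and at -0.75 over 18 of 22 genes with those of 0 UMIs at their limit. The cytotoxicity list, at a median of 0.20 (-0.42 to 0.70), was not set apart as a whole, with 8 of 13 members higher and 5 lower. Among the higher members were Gzmb and Gzma (log2 ratios with the prior 2.72 and 1.66). In cluster 6, 28.9% (19.8 to 39.4) of cells with a clone belonged to a clone seen in skin, a share that sampling more skin cells could raise. A pair of shared clones had the same TRB CDR3, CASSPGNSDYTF, with the TRA CDR3 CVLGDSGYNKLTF in one and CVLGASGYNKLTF in the other. The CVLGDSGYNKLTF pair, with 7 skin cells in the shared clone, was also encoded by other nucleotide sequences in skin, in clones of 6 and 5 cells.

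The sharing of clones between tissues was weighed against passage of molecules between libraries and against unrelated cells with like sequences. Of 231 skin cells of shared clones, 0 (0%) had a barcode carrying that TRB in the lymph node table. The upper limit of 1.58% lay below the bound of 5% set for it. However, only 64 of these cells could have matched, so most could not, and the skin test alone decides nothing. Of 40 lymph node cells of shared clones, 0 had such a barcode in the skin table, with an upper limit of 8.81%. The lymph node result argues against molecules passed between the libraries as the source of most of this sharing. The planned test of like sequences went the other way from the bound of 20% set for it: of 56 TRB amino acid sequences in both tissues, 26 (46.4%, 33.0 to 60.3) had no clone shared by nucleotide sequence and TRA, so sharing judged by TRB amino acids alone may often come from unrelated cells. For sharing on both chains, 1 of 31 paired sequences was encoded by more than 1 nucleotide sequence (3.23%, 0.0816 to 16.7), against 22 of 56 TRB sequences (39.3%, 26.5 to 53.2), which argues against that explanation for most of the pairs. Presence of related cells in both tissues stays open as a hypothesis, along with carry-over of cells.

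The expression of shared-clone cells was weighed against 3 explanations. No shared clone held more than 2 of the 28 cells in the gene table, which argues against a dominant clone. Without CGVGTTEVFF, 1 of a pair of clones with 2 cells, the residency median was 1.5 against 1.52. With every clone weighted equally it was 1.35, but clones this small could hardly have moved it. Against expanded LN-only clones the residency median was 2.0 (0.90 to 2.75), which argues against expansion in the lymph node as the whole cause. Clone size was not matched in either tissue, so its part was not settled. This median was 1.04 to 1.76 over the alternatives fixed before, and the interval of the lowest, from thinned cells, reached 0. Skin cells carried over into the lymph node suspension could not be excluded: the dissociation stress list, which the warm digest of skin may raise, had a median of -0.076 (-0.77 to 0.16), with members going both ways, and decides nothing. No biological explanation was tested.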
